A study of Homo sapiens with 7 samples.

How the data were processed

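The deposited tables held 1 normalized intensity per probe for each of 7 arrays and 31741 probes. The sample labels give the cell line, interferon, dose and time. The deposited text does not say how the values were scaled or which scanner was used, so both are not given in the sources used here. A test on the values showed that each array's intensity was, within a tolerance of 0.05 units, a whole number of units times 1 scale factor (0.8192 to 1.37253), and that 39 to 61 values per array were 0 or below. The number of arrays, 1 per condition, limits precision.

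Values were set to at least 1 and turned to log2. The medians differed by 0.357 log2 units between arrays, above a limit of 0.2 set in advance, so quantile normalization was used (numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15). Probe symbols came from the deposited platform table and were compared with a gene reference: 24740 probes had 1 symbol, 977 several and 6024 none. Of those with 1 symbol 22722 were current, 1948 were updated and 70 were kept as written. The probe with the highest mean stood for each of 18336 genes, and 12835 genes with a mean above the 30th percentile were kept.

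Differences between single arrays were called at 2-fold. limma 3.58.1 in R 4.3.3 compared the 6 treated arrays with the untreated one, 16 h with 6 h with a block for interferon, and the interferons with a block for time, using a variance trend and Benjamini-Hochberg adjustment at 0.05. The blocked models had 2 residual degrees of freedom and the model of treatment 5. The medians of 21 gene lists, written from general knowledge, were set against 10000 random lists matched on 20 level bins, and those outside the 2.5 to 97.5 percentiles counted as past the random range. The lists were antiviral effectors, interferon receptors and JAK-STAT, negative regulators of interferon signalling, nucleic acid sensing, MHC class I antigen presentation, interferon-γ type targets, chemokines and cytokines, NF-κB targets, unfolded protein response, hepatocyte secreted proteins, hepatocyte metabolism and transport, cholesterol biosynthesis, cell cycle, p53 targets and apoptosis, immediate early genes, hypoxia and glycolysis, heat shock and metallothioneins, leukocyte, fibroblast and stellate, and endothelial markers, and housekeeping genes. Figures were drawn with matplotlib 3.10.9.

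Genes were named by a rule: for each interferon the 10 highest and 5 lowest at both times by the smaller of the 2 differences, 4 members of each list with the largest mean difference, up to 5 per direction for IFN-λ4 against each other interferon and for 16 h against 6 h with all 3 interferons, and the receptor and signalling genes IFNAR1, IFNAR2, IFNLR1, IL10RB, STAT2, IRF9, IRF1 and IRF7. Groups, comparisons, lists, this rule and most of the variations below were fixed before the data were examined.

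Results were recomputed with median centring, no filter on dim genes, leaving out genes below the 50th percentile, setting low values to the 30th percentile, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, no variance trend, no block, and leaving out each interferon. Keeping the deposited scaling, leaving out genes with an extreme spot on the untreated array, and leaving out the IFN-α array of 16 h were chosen after seeing the data. Lists in these variations used 2000 random lists.

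The steps were tested on simulated data with 12835 genes. Each changed gene was shifted equally on all arrays of its side, with noise from the residuals of the blocked model of times. Real responses also differed among interferons and times, which widens the real spread of treated against untreated arrays. For genes with such responses the shares below for that comparison can be too high. limma recovered 52.2% of 2-fold changes and 98.5% of 4-fold changes between treated and untreated arrays, 88.1% and 100% between times, 44.8% and 100% between IFN-λ4 and IFN-λ1, and 61.2% and 100% between IFN-λ4 and IFN-α, with 18, 24, 9 and 4 false calls. The 2-fold call at both times recovered 35.8% and 98.5%, with 30 false calls. Of 100 unshifted lists 6 were past the random range, and 100 of 100 shifted by 0.5 were. These lists were random genes with independent noise. Genes of a real list may vary together on an array, which would put unshifted lists past the range more often. That was not simulated, so small list medians past the range carry no known false rate.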

Results

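Huh7, a human hepatoma cell line, was treated with IFN-α at 10 IU/ml, IFN-λ1 at 20 ng/ml or IFN-λ4 at 20 ng/ml for 6 h or 16 h, and messenger RNA was measured on Cy5 arrays. IFN-α is a type I interferon that binds the receptor chains IFNAR1 and IFNAR2. IFN-λ1 and IFN-λ4 are type III interferons that bind IFNLR1 and IL10RB. The set held 7 arrays, 1 for each interferon at each time and 1 for untreated cells at 0 h. The median intensity of the 31741 probes lay between 494 and 633 across the arrays and the upper quartile between 3081 and 3415. After matching to gene symbols and leaving out dim genes, 12835 genes were compared. No condition was repeated, so differences between single arrays had no replicate check and carry no p-value, and the number of arrays limits their precision. The median residual SD of the blocked fit of times was 0.22 log2 units, which would give a difference between 2 arrays an SE of 0.31. With no repeated condition, that residual holds interferon-by-time differences as well as array error, so array error was not measured. IFN-α and IFN-λ doses were in different units, and the untreated cells were not matched to the treated cells for time in culture.

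Antiviral genes were higher after treatment, whichever interferon was used. The untreated arm was 1 array, so the p-values below hold no spread between untreated cultures, and the spread they use holds the differences among interferons and times. The smallest p-values of this comparison belonged to 5 genes with a single extreme untreated spot. IFI6, an interferon-induced mitochondrial protein, rose by 6.22 ± 0.71 log2 units (SE) in the 6 treated arrays against the untreated one, with an adjusted p of 0.00674 from limma with Benjamini-Hochberg adjustment. ISG15, the ubiquitin-like modifier, rose by 4.498 ± 0.41 (adjusted p = 0.00127, limma), and OAS1, which makes the oligoadenylates that activate RNase L, rose by 5.62 ± 0.59 (adjusted p = 0.0043, limma). IRF9, the DNA-binding subunit of the transcription factor complex formed downstream of both receptors, rose by 2.43 ± 0.31 (adjusted p = 0.0158, limma). Each of these genes was higher than untreated in 6 of 6 treated arrays. The RNA sensor IFIH1 (3.87 ± 0.55), the GTPase MX1 (3.94 ± 0.50), OAS3 (4.76 ± 0.64), EPSTI1 (5.25 ± 0.59), the RNA-binding protein IFIT1 (6.02 ± 0.89) and the metalloproteinase MMP11 (1.59 ± 0.23) also rose. OAS3, MX1 and MMP11 lie outside the rule for named genes and were chosen after their values were seen.

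Of the 12835 genes, 14 rose and 1 fell in this limma comparison of 6 treated arrays with 1 untreated array, and 257 had an unadjusted p under 0.05. The other 5 of these 15 genes rested on a single extreme spot of the untreated array. LRRC20 read -1.99 there against 1381 to 1634 on the treated arrays, MPEG1 -5.98 against 1729 to 2667, TMEM165 1.99 against 1209 to 2263 and MAP3K2 20.9 against 2316 to 4012, while ADIPOQ read 33081 against 208 to 273. A second probe of MPEG1 read 58.8 on the untreated array and 50.1 to 83.6 on the treated ones. MAP2K4, named by the size rule, read 3.99 on the untreated array and 0.819 on the IFN-λ1 array of 6 h against 4127 to 5104 on the others. The count of genes that rose was 36 without the IFN-α arrays and 9 without the IFN-λ4 arrays.

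Interferon-stimulated antiviral effectors were higher than untreated on every treated array, under each of the 3 scalings tried. Of 61 listed genes, 51 were measured above the dim level. Their median difference was 3.43 log2 units with IFN-α at 6 h and 1.34 at 16 h, 1.75 and 1.89 with IFN-λ1, and 1.77 and 1.65 with IFN-λ4, each above all 10000 random lists of matched level. At least 2-fold higher were 45 members with IFN-α at 6 h and 29 at 16 h, 33 and 36 with IFN-λ1, and 35 on both IFN-λ4 arrays, while 1 member was at least 2-fold lower with IFN-α at 16 h. IFITM1, which blocks viral entry, was 169-fold higher with IFN-α at 6 h, 22.2-fold with IFN-λ1 and 25.7-fold with IFN-λ4. In the comparison of all treated arrays with untreated, 8 of the 51 members rose when adjusted over all genes and 28 rose when adjusted over the list alone (limma). The listed genes RSAD2, IFI27, IFIT2, IFI44, SAMD9L, DDX60, TRIM22 and UBA7 were dim and were not part of these counts.

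**Figure D1:**
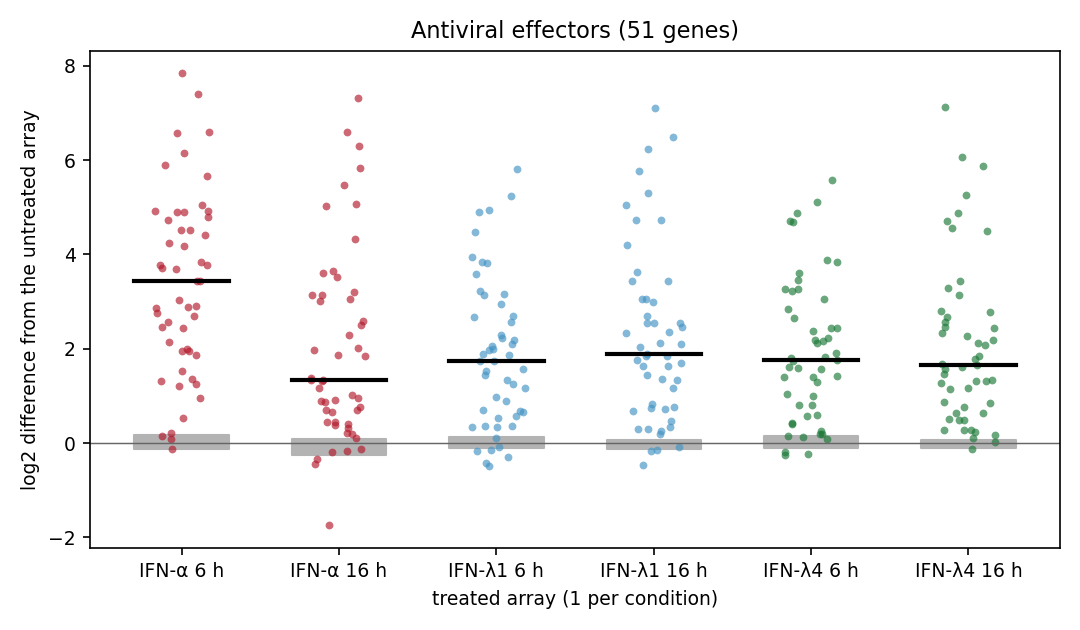
Difference from untreated (log2, vertical axis) of the 51 antiviral effectors measured above the dim level on each of the 6 treated arrays (horizontal axis). Points are genes, the black line is the median (3.43 for IFN-α at 6 h, the highest, and 1.34 for IFN-α at 16 h, the lowest), and the grey band is the central range of medians of random lists, above which every median lay under each of the 3 scalings tried.

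With IFN-α, the question was which genes a type I interferon moved in hepatoma cells. OAS1 was 95.9-fold higher than untreated at 6 h and 79.1-fold at 16 h, IFI6 was 70.7-fold and 96.7-fold higher, and IFITM1 was 169-fold and 160-fold higher. Metallothioneins, small proteins that bind zinc and copper, stood beside them: MT1E was 61.9-fold higher at 6 h and 95.7-fold at 16 h, and MT1B was 167-fold and 296-fold higher. Metallothionein genes are close paralogs, and their probes may share signal. MT1B read 212 on the untreated array, below that array's median of 609, so its folds rest on a low value. Lower than untreated at both times were SLC39A10, a zinc importer, by log2 differences of -2.36 and -3.12, the receptor kinase GRK2 (-3.76 and -2.31), ATAD3B (-2.53 and -2.42) and WDR81 (-2.48 and -2.11). At 6 h 501 genes were at least 2-fold higher and 363 lower, at 16 h 738 and 443, and at both times 266 and 110. A simulated unchanged array gave 65.3 higher and 66.1 lower genes, and 14.1 and 14.2 at both times. Its spread was the residual of the blocked fit, which holds interferon-by-time differences as well as array error. Of the genes called at 6 h 58.0% were higher, against 72.7% with median centring and 39.1% with the deposited scaling, so the balance between higher and lower genes turned with the scaling. Under median centring the median of all genes lay at 0.22 on this array, at 0.22 on the IFN-λ4 array of 6 h and at -0.17 on the IFN-α array of 16 h, where the deposited scaling gave -0.12.

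Beyond the antiviral effectors, IFN-α arrays had higher medians for antigen presentation and inflammatory genes and a lower median for the unfolded protein response. TAP1, the peptide transporter of MHC class I loading, was 28.1-fold higher at 6 h and 10.5-fold at 16 h, and the immunoproteasome subunits PSMB9 (20.1-fold and 22.4-fold) and PSMB8 (7.69-fold and 17.8-fold) were also higher. The 15 measured MHC class I genes had medians of 0.64 and 0.79, above the random range at both times. The NF-κB targets, 14 genes, had medians of 0.98 and 0.30, with RELB 5.42-fold and TNFAIP3, a brake on NF-κB, 4.59-fold higher at 6 h. Among 11 nucleic acid sensors the medians were 1.02 and 0.53, and RIGI was 34.0-fold higher at 6 h and 3.29-fold at 16 h. These sensor medians no longer stood above the random range when genes below the 50th percentile were left out (0.36 and 0.19). CXCL10, a chemokine that draws T cells, was 37.3-fold and 12.9-fold higher. The 15 chemokines and cytokines stood above the random range at 16 h with a median of 0.28, and at 6 h (0.18) only under median centring (0.86), the deposited scaling (0.56) or a mean over probes (0.35). Their mean was nevertheless larger at 6 h, at 1.045 with 6 members at least 2-fold higher and 0 lower. At 16 h it was 0.465, with 3 higher and 2 lower. The unfolded protein response, 19 genes, had medians of -0.43 and -0.76, below the random range under each scaling. SDF2L1, an endoplasmic reticulum chaperone partner, was 1.79-fold lower at 6 h and 2.91-fold lower at 16 h, and the stress-induced kinase-like protein TRIB3 was 1.63-fold and 2.71-fold lower. At each time 1 member was at least 2-fold higher, against 2 lower at 6 h and 8 at 16 h. ATF3 was 3.63-fold higher at 6 h, and PPP1R15A, outside the rule for named genes, was 3.86-fold higher at 16 h.

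Stress proteins split with time on the IFN-α arrays. The 16 heat shock genes and metallothioneins had a median of 0.82 at 6 h and -0.45 at 16 h, both outside the random range, while their mean at 16 h was 0.75 because 4 members were at least 2-fold higher and 6 lower. MT2A was 13.4-fold and 17.2-fold higher, and MT1X was 40.8-fold and 50.3-fold higher. The median at 16 h lay inside the random range without the filter on dim genes (-0.25). Immediate early genes, 21 members, had medians of 0.23 at 6 h and -0.41 at 16 h, and both calls were lost under the 2 other scalings. JUN was 3.004-fold and 2.65-fold higher.

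Liver and growth genes were compared next on the IFN-α arrays. Among 23 hepatocyte secreted proteins the median was -0.21 at 6 h, but 0.20 under median centring, and 0.00 at 16 h. APOB, the structural protein of very low density lipoprotein, was 1.56-fold lower at both times. The 18 genes of hepatocyte metabolism and transport had medians of -0.28 and -0.11, the first below the random range except without the filter on dim genes (-0.19), and the asialoglycoprotein receptor subunit ASGR1 was 1.30-fold and 2.41-fold lower. Cholesterol biosynthesis, 18 genes, had a median of -0.36 at 6 h that turned to 0.04 under median centring, and -0.23 at 16 h. At 6 h 5 of its members were at least 2-fold lower (MVK, MVD, IDI1, INSIG1 and HSD17B7) and 0 higher. MVK was 5.93-fold and 2.05-fold lower, and MVD 4.36-fold and 1.64-fold lower. Both are enzymes of the mevalonate pathway. For 31 cell cycle genes the median of -0.25 at 6 h turned to 0.11 under median centring, and it was -0.14 at 16 h. CCNA2, the S phase cyclin, was 1.90-fold and 1.39-fold lower.

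With IFN-λ1, antiviral genes led the list at both times once MPEG1, LRRC20, TMEM165 and MAP3K2, which stood above them through the untreated spots, were set aside. IFI6 was 37.5-fold higher than untreated at 6 h and 137-fold at 16 h, IFIT1 was 56.4-fold and 90.5-fold higher, and OAS1 was 30.04-fold and 54.5-fold higher. EPSTI1 was 30.9-fold and 33.2-fold higher, and MT1E 17.3-fold and 9.61-fold. At 6 h 137 genes were at least 2-fold higher and 85 lower, at 16 h 123 and 30, and at both times 81 and 14. Simulated unchanged arrays gave 14.2 genes lower at both times. Their spread was too wide to judge the 14 genes here, since they gave 66.1 lower genes per array, against 30 at 16 h. OR6P1, an olfactory receptor gene, was 6.20-fold and 5.15-fold lower, FAM131B 3.31-fold and 3.07-fold, CD164L2 3.58-fold and 2.86-fold, and REXO1L1P 3.04-fold and 2.69-fold. Of the genes called at 16 h 80.4% were higher, against 67.7% with the deposited scaling.

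With IFN-λ4, IFIT1, IFI6, OAS1, EPSTI1 and IFITM1 followed the same 4 genes and MAP2K4, which rested on the untreated spots. IFI6 was 34.6-fold higher than untreated at 6 h and 139-fold at 16 h, IFIT1 was 47.5-fold and 67.1-fold higher, and OAS1 29.4-fold and 38.5-fold. ISG15 was 14.8-fold and 22.5-fold higher, and MT1E 20.1-fold and 13.2-fold. At 6 h 262 genes were at least 2-fold higher and 158 lower, at 16 h 127 and 26, and at both times 103 and 4. With the deposited scaling 46 were lower at 16 h and 11 at both times, and simulated unchanged arrays gave 14.2 lower at both times. The simulated spread was again too wide to judge the lower genes, at 66.1 lower genes per array against 26 at 16 h. The 4 lower genes were CCKBR (2.90-fold and 2.62-fold lower), CD164L2 (2.45-fold and 2.25-fold), the proteasome subunit PSMA1 (2.34-fold and 2.16-fold) and ADIPOQ, which rested on the untreated spot. Of the genes called at 6 h 62.4% were higher, against 80.4% with median centring and 38.5% with the deposited scaling, where most were lower. At 16 h 83.0% were higher, against 70.1% with the deposited scaling.

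Smaller gene groups were also higher on the IFN-λ arrays. The 15 MHC class I genes had medians of 0.37 and 0.33 with IFN-λ1 and 0.19 and 0.45 with IFN-λ4, of which the IFN-λ4 median at 6 h lay inside the random range. TAP1 was 4.09-fold and 4.33-fold higher with IFN-λ1 and 4.19-fold and 3.40-fold with IFN-λ4. NF-κB targets had medians of 0.33 and 0.21 with IFN-λ1 and 0.53 and 0.21 with IFN-λ4, all above the random range, although the IFN-λ1 median at 16 h was not with a mean over probes (0.16). Heat shock genes and metallothioneins had medians of 0.29, 0.27, 0.31 and 0.23 in the same order, all above it, and MT2A was 7.002-fold and 4.70-fold higher with IFN-λ1. The 11 nucleic acid sensors had medians of 0.26 and 0.01 with IFN-λ1, inside the random range, and of 0.38 and 0.18 with IFN-λ4, just above it. The IFN-λ4 calls were lost under median centring, and with the deposited scaling the median at 16 h turned to -0.04. Immediate early genes had medians of 0.38 and 0.16 with IFN-λ1, both above the random range, and 0.48 and 0.10 with IFN-λ4, the first above it. Chemokines and cytokines stood above it only with IFN-λ4 at 6 h (0.33), a call that both other scalings ended (0.39 and 0.13) and that turned to -0.019 without genes below the 50th percentile. TNFSF10, which encodes the death ligand TRAIL, was 2.90-fold to 5.01-fold higher on the IFN-λ arrays.

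Interferon receptor and signalling genes were also compared with untreated. IFNAR1, IFNAR2 and IL10RB differed from untreated by log2 values between -0.60 and 0.46 on every treated array. IFNLR1 was dim, with an intensity of 281 on the untreated array and 137 to 297 on the treated ones, and IRF7 was dim as well. STAT2, a subunit of the interferon-activated complex, was 6.23-fold higher with IFN-α at 6 h and 1.91-fold to 2.17-fold higher on the other treated arrays. The transcription factor IRF1 was 12.4-fold higher with IFN-α at 6 h and 2.24-fold to 2.81-fold on the others. The kinase TYK2 was 3.68-fold lower with IFN-α at 6 h. The 14 receptor and JAK-STAT genes stood above the random range with IFN-α at 6 h alone (median 0.40). IRF9 rose by the adjustment over all genes and was the only one adjusted over the list alone. For the 12 negative regulators no median left the random range (-0.08 to 0.11), but USP18, which blocks the type I receptor, was 2.13-fold to 8.73-fold higher on every treated array. Adjusted over the list alone it was the 1 member that rose, at 2.16 ± 0.58, and none of the 12 rose adjusted over all genes (limma). With IFN-α at 6 h 3 members were at least 2-fold higher: USP18, SOCS2 (5.28-fold) and SOCS3 (3.12-fold), the last outside the rule for named genes. SOCS1 was lower with IFN-α, 2.06-fold at 6 h and 4.21-fold at 16 h.

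Other fixed lists moved little on the IFN-λ arrays. Of 22 listed targets of interferon-γ type, 9 were measured above the dim level. These 9 had no median outside the random range on any array, although CXCL10 is among them. With IFN-α at 6 h their median was -0.13 and their mean 0.85. Most of the list was dim, so the medians do not describe it as a whole. Of the dim members, APOL6 was 2.06-fold to 7.66-fold higher on every treated array, and GBP2 was 1.01-fold to 2.33-fold lower. APOL6 and GBP2 were chosen after their values were seen. Unfolded protein response medians were -0.08 and 0.04 with IFN-λ1 and -0.15 and 0.10 with IFN-λ4, inside the random range, with a mean of 0.08 for IFN-λ4 at 6 h. Cholesterol biosynthesis had a median of -0.22 with IFN-λ4 at 6 h that turned to 0.13 under median centring, and the cell cycle list a median of -0.18 with IFN-λ1 at 6 h. The 20 p53 targets and apoptosis genes stood above the random range with IFN-λ1 at 16 h (0.22), and 20 hypoxia and glycolysis genes with IFN-λ4 at 16 h (0.15). Markers of other cell types, 9 for leukocytes, 6 for fibroblasts and stellate cells and 6 for endothelium, stayed inside it on all arrays except the leukocyte list with IFN-α at 16 h (0.55), where the B cell gene MS4A1 was 7.93-fold higher. That call was lost when genes below the 50th percentile were left out (0.13). The 11 housekeeping genes stayed inside it (-0.02 to 0.09), but GAPDH was 2.997-fold lower with IFN-α at 6 h. Adjusted over the list alone, 3 metallothioneins rose (MT1E, MT1X and MT2A), as did TNFSF10, against none of them adjusted over all genes (limma).

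**Figure D2:**
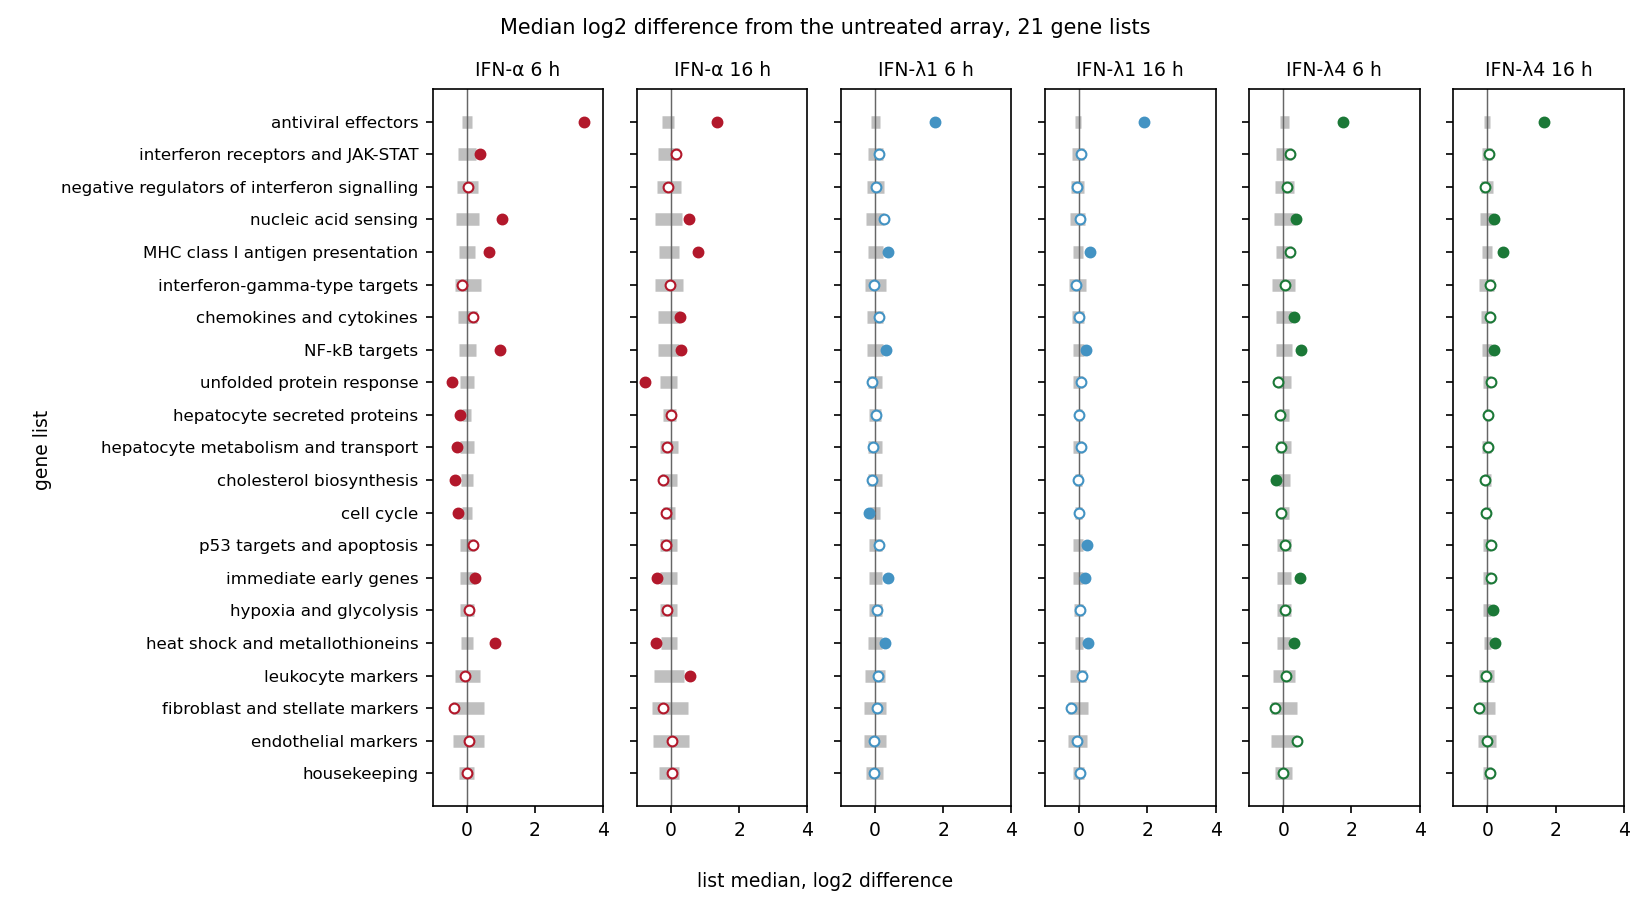
Median difference from untreated (log2) of the 21 fixed gene lists on each of the 6 treated arrays. Grey bars are the central range of medians of random lists and filled points lie outside it, as 12 lists did for IFN-α at 6 h and 6 for IFN-λ4 at 16 h; the medians at 6 h for cholesterol biosynthesis (IFN-α and IFN-λ4), for cell cycle (IFN-α) and for hepatocyte secreted proteins (IFN-α) changed sign under median centring, and that for nucleic acid sensing with IFN-λ4 at 16 h under the deposited scaling.

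**Figure D3:**
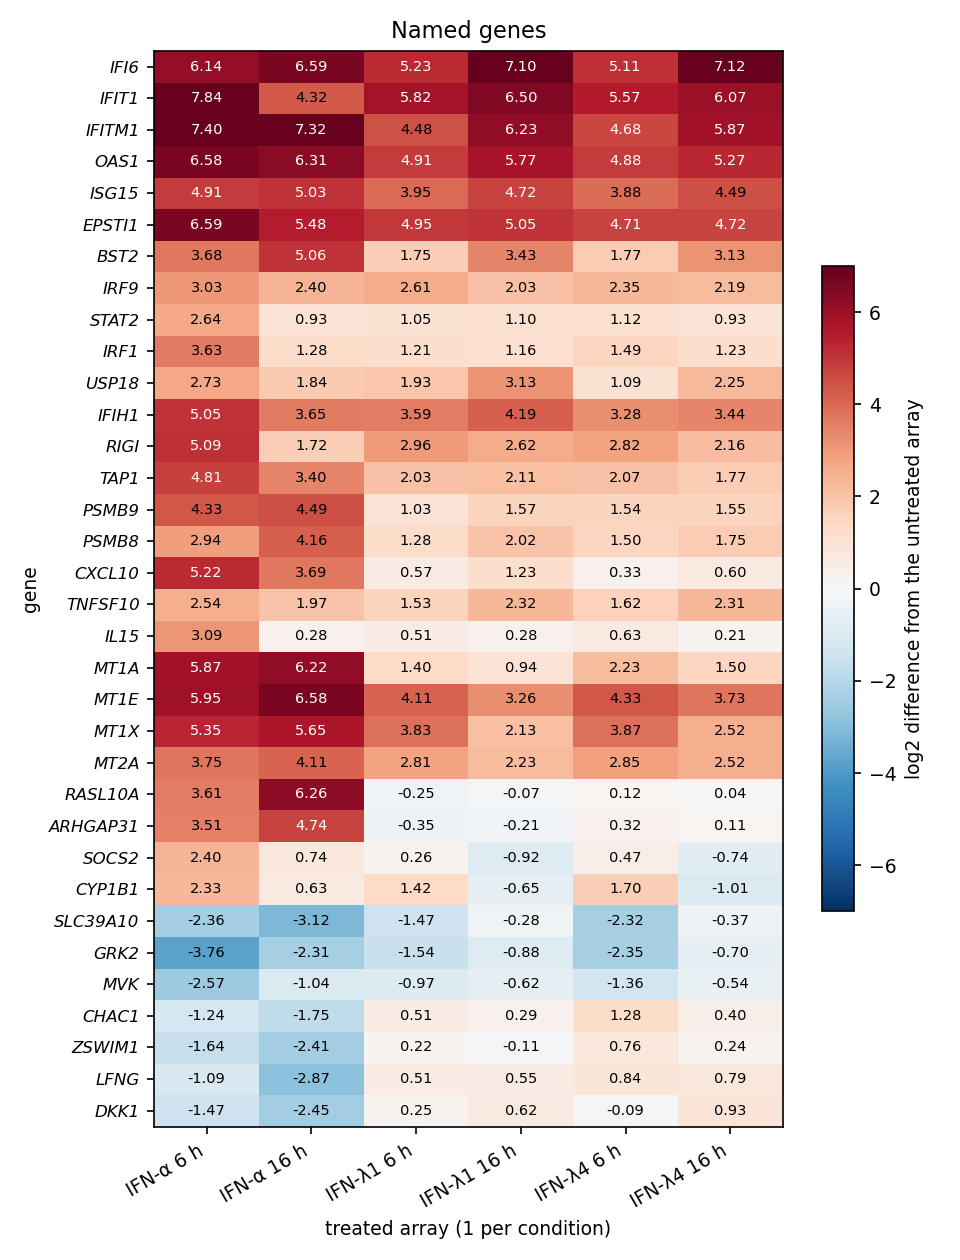
Difference from untreated (log2, colour scale) of named genes (vertical axis) on the 6 treated arrays (horizontal axis). IFI6 ranged from 5.11 to 7.12 over the arrays, and RASL10A was 6.26 with IFN-α at 16 h but between -0.25 and 0.12 on the IFN-λ arrays.

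The higher genes of the 3 interferons overlapped. At both times 58 genes were at least 2-fold higher with all 3, among them IFI6, OAS1, ISG15, IFIT1 and IRF9, and 1 gene, ADIPOQ, was lower with all 3. The 58 and the shared higher genes of each pair also hold LRRC20, MPEG1, TMEM165 and MAP3K2, which rested on the untreated spots. ADIPOQ rested on such a spot too, and is among the shared lower genes of each pair. IFN-λ4 and IFN-λ1 shared 73 higher genes, of 103 and 81, IFN-λ4 shared 76 with the 266 of IFN-α, and IFN-λ1 shared 60 with them. Independent lists would share 0.65, 2.13 and 1.68 genes, and simulated unchanged arrays set against the same untreated array shared 3.37. Of lower genes IFN-λ4 and IFN-λ1 shared 3, against 0.00436 for independent lists and 3.95 in the simulation, and each of the other pairs shared 1, against 0.0343 for IFN-λ4 and 0.12 for IFN-λ1. The simulated spread was too wide to judge these lower genes, as above. All comparisons used the 1 untreated array, which could not be divided, so part of the excess may come from the shared array.

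Across genes, which are not independent replicates, the differences from untreated with IFN-λ4 followed those with IFN-λ1 at r = 0.71 (rho 0.61) at 6 h and r = 0.79 (rho 0.67) at 16 h. IFN-λ4 and IFN-α gave r = 0.68 (rho 0.53) at 6 h and 0.42 (rho 0.27) at 16 h, and IFN-λ1 and IFN-α gave 0.58 (rho 0.41) and 0.46 (rho 0.32). The covariances were 0.16 and 0.14 for the IFN-λ pair, 0.22 and 0.13 for IFN-λ4 with IFN-α, and 0.17 and 0.14 for IFN-λ1 with IFN-α. Unchanged arrays simulated against 1 shared untreated array gave r = 0.50, rho 0.48 and a covariance of 0.06. Both IFN-α pairs at 16 h lay below that r and rho, and IFN-λ1 with IFN-α at 6 h lay below that rho. Every covariance lay above the simulated one. Part of each relation may come from the shared array, and r and rho at 16 h show none beyond it for the IFN-α pairs. As above, the simulated spread holds interferon-by-time differences as well as array error.

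**Figure D4:**
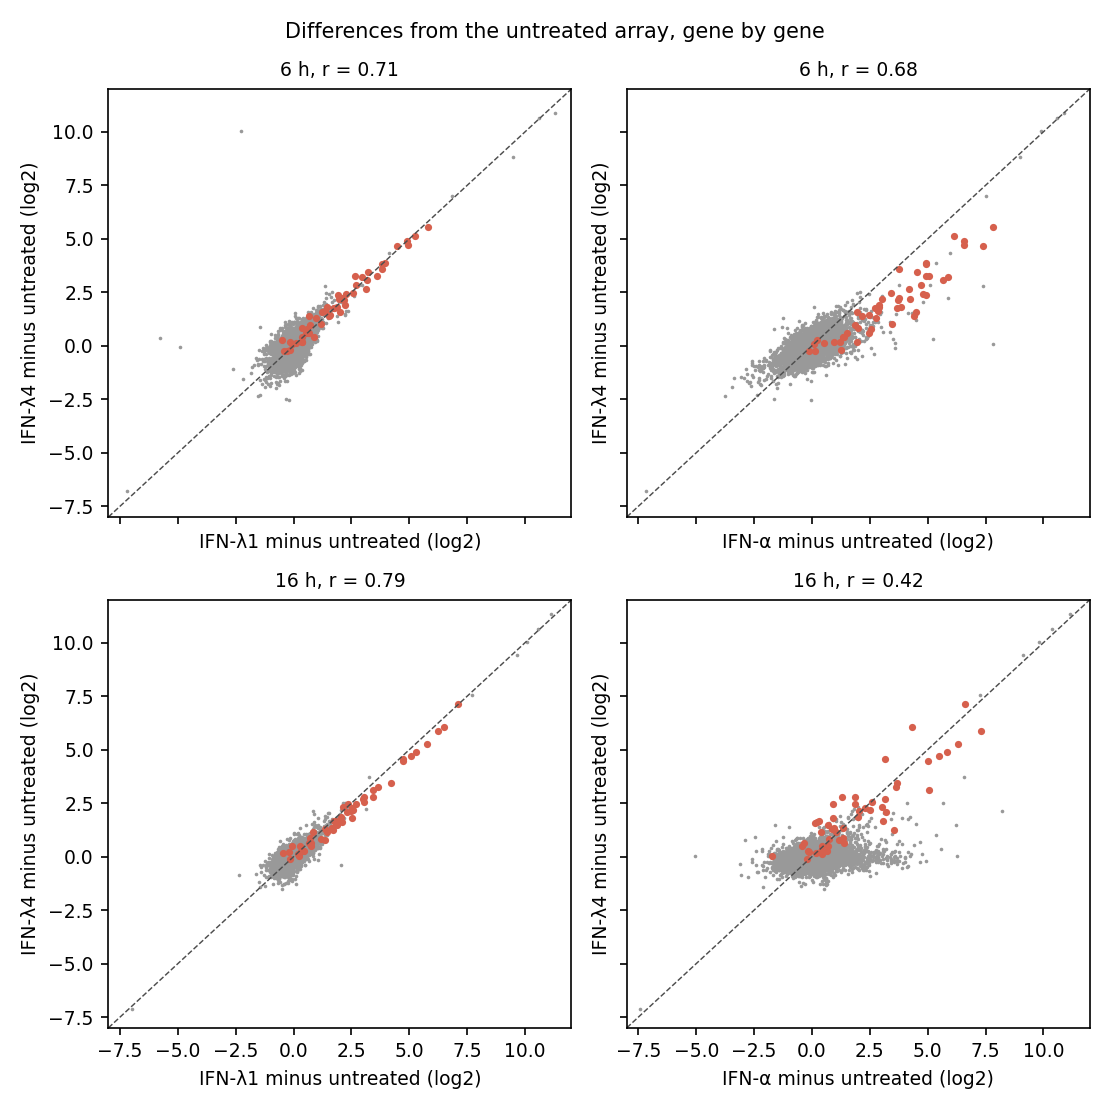
Difference from untreated (log2) with IFN-λ4 (vertical axes) against that with IFN-λ1 or IFN-α (horizontal axes) at 6 h and 16 h. Each point is 1 of 12835 genes, antiviral effectors are red and the dashed line marks equal differences; r was 0.71 and 0.79 for IFN-λ1, and 0.68 and 0.42 for IFN-α, where many points at 16 h lay along the IFN-α axis.

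Whether IFN-λ4 acted differently from IFN-λ1 was asked at matched times and the same dose in ng/ml. Antiviral effectors had a median difference, IFN-λ4 minus IFN-λ1, of 0.03 at 6 h, inside the random range, and of -0.25 at 16 h, below all random lists, with none of the 51 at least 2-fold apart at either time. IFIT1 was 67.1-fold above untreated with IFN-λ4 and 90.5-fold with IFN-λ1 at 16 h, and USP18 was 4.75-fold and 8.73-fold above. At least 2-fold higher with IFN-λ4 at both times were 4 genes and lower 0: OR6P1 by 1.55 and 1.50 log2 units, the metallothionein MT1B by 1.42 and 1.31, the sensory receptor gene MRGPRX1 by 1.32 and 1.02, and the neuronal transcription factor NEUROD2 by 1.13 and 1.32. OR6P1 was below untreated with both interferons. Over both times, limma found 0 genes higher and 0 lower after Benjamini-Hochberg adjustment, with 304 at an unadjusted p under 0.05, and adjusted over the list alone no fixed list had a gene past the threshold. Without the IFN-α array of 16 h, which enters this fit only through the spread and the time block, limma found 2 higher and 0 lower, with 1748 at an unadjusted p under 0.05 and 1 residual degree of freedom. The interval of each difference reached a median of 0.53 log2 units to either side (95% level), and for 11236 genes (87.5%) the interval lay within 2-fold either way. Of the 51 antiviral effectors 25 had such an interval, and theirs reached a median of 0.88 to either side around a median difference of -0.10. For IFI6 the difference was -0.05 ± 0.38 (SE), for ISG15 -0.15 ± 0.21 and for IFIT1 -0.34 ± 0.93. The spread behind these SEs and intervals came from all 6 treated arrays, so it holds the time course of IFN-α as well. IFIT1, for example, stood 7.84 log2 units above untreated with IFN-α at 6 h and 4.32 at 16 h. The intervals therefore do not measure the uncertainty between the 2 IFN-λ alone.

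At 6 h the unfolded protein response was higher with IFN-λ4 than with IFN-λ1 by a median of 0.20, above the random range, but not past it under median centring (0.32) or the deposited scaling (0.08). Endothelial markers (0.42) and fibroblast and stellate markers (-0.31), 6 genes each, also left the range, but not without the filter on dim genes (0.14 and -0.10), and neither did at 16 h. Cholesterol biosynthesis (-0.14) and cell cycle (-0.09) were lower but turned to 0.08 and 0.14 under median centring.

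PSMB9, MT1A and MT1B were lower with IFN-λ4 and with IFN-λ1 than with IFN-α. PSMB9 was lower with IFN-λ4 by a log2 difference of -2.87 ± 0.23 (SE, adjusted p = 0.0295, limma with Benjamini-Hochberg adjustment) and with IFN-λ1 by -3.11 ± 0.23 (adjusted p = 0.0174, limma), with each IFN-λ array below the IFN-α array at both times. MT1A was lower by -4.18 ± 0.28 and -4.88 ± 0.28 and MT1B by -5.33 ± 0.37 and -6.70 ± 0.37, probes that may share signal with other metallothioneins. ARHGAP31 was lower by -3.90 ± 0.35 and -4.40 ± 0.35, since it stood 11.4-fold and 26.6-fold above untreated with IFN-α and near untreated with IFN-λ. Higher with IFN-λ4 than with IFN-α were CHAC1, a glutathione-degrading enzyme of the unfolded protein response, by 2.34 ± 0.23 and ZSWIM1 by 2.53 ± 0.22. In all limma found 2 genes higher and 8 lower with IFN-λ4 than with IFN-α, with 1744 at an unadjusted p under 0.05, and 0 higher and 6 lower with IFN-λ1 than with IFN-α, with 1889. For IFN-λ4 the counts were 1 higher and 5 lower with the deposited scaling or without the variance trend, and 0 and 3 without genes below the 50th percentile (1003 at an unadjusted p under 0.05), and for IFN-λ1 they were 2 and 21 with median centring and 0 and 3 without genes below the 50th percentile (1135). The remaining lower genes were SLC15A3 (-2.64 and -2.58) and the oxidase DUOX1 (-3.13 and -3.85) with both, and UBE2L6 (-1.93), the conjugating enzyme for ISG15, and the replication protein RPA3 (-2.45) with IFN-λ4. SLC15A3, DUOX1, UBE2L6 and RPA3 were chosen after their values were seen. IFN-λ4 had 45 genes at least 2-fold higher and 140 lower than IFN-α at both times, and IFN-λ1 had 34 and 160. CXCL10 was lower with IFN-λ4 by log2 differences of -4.90 at 6 h and -3.08 at 16 h, RASL10A by -3.49 and -6.22, and the Wnt inhibitor DKK1 was higher by 1.37 and 3.38, as was LFNG, which modifies Notch, by 1.94 and 3.67.

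Antiviral effectors were lower with IFN-λ than with IFN-α at 6 h, and went both ways at 16 h. The median difference from IFN-α at 6 h was -1.25 with IFN-λ4, where 34 of 51 members were at least 2-fold lower, and -1.42 with IFN-λ1, where 33 were. At 16 h it was -0.01 with IFN-λ4 (mean 0.08), inside the random range, with 8 members at least 2-fold higher and 6 lower, and 0.24 with IFN-λ1, above it, with 12 higher and 4 lower, but not without the filter on dim genes or with low values set to the 30th percentile (0.19 in both). Over both times 10 members were lower than with IFN-α when adjusted over the list alone, for each IFN-λ, and 0 when adjusted over all genes, where 14 and 15 had an unadjusted p under 0.05 (limma). Adjusted over the list alone, MHC class I genes gave 1 higher and 5 lower with IFN-λ4 and 3 higher and 7 lower with IFN-λ1, the lower ones including TAP1 (-2.19 and -2.03) and PSMB8 (-1.93 and -1.90) and the higher ones being CALR (0.82 and 0.66) with both and ERAP1 (0.78) and PDIA3 (0.75) with IFN-λ1, against 1 lower, PSMB9, adjusted over all genes for each.

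The unfolded protein response was higher with IFN-λ than with IFN-α at both times, by medians of 0.36 and 0.97 for IFN-λ4 and 0.35 and 0.80 for IFN-λ1. HSPA5, the main chaperone of the endoplasmic reticulum, was higher with IFN-λ4 by 1.35, ASNS, which makes asparagine, by 1.60 and SDF2L1 by 1.09, whereas PPP1R15A was lower (-1.44). Adjusted over the list alone, 6 members were higher and 1 lower with IFN-λ4, and 8 and 2 with IFN-λ1, against 1 (CHAC1) and 0 higher adjusted over all genes. NF-κB targets at 6 h were lower by medians of -0.53 for both IFN-λ (at 16 h -0.09 and -0.06, inside the random range), chemokines and cytokines by -0.83 and -0.86 (at 16 h -0.08 and 0.00, inside the random range), and nucleic acid sensors by -0.65 and -0.77 (at 16 h -0.22 and -0.04, also inside it). Heat shock genes and metallothioneins were lower at 6 h (-0.88 and -0.90) and higher at 16 h (0.53 and 0.49), where the means were -0.03 and -0.11. HSPA5, ASNS and PPP1R15A were chosen after their values were seen. IFN-α rested on 1 array per time. Without its array of 16 h, limma found 685 genes higher and 778 lower with IFN-λ4 than with IFN-α and 757 and 1028 with IFN-λ1, with 1 residual degree of freedom and IFN-α represented by its array of 6 h alone.

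Antiviral effectors were lower at 16 h than at 6 h with IFN-α, by a median of -1.10, with 28 of 51 at least 2-fold lower. With IFN-λ1 they were higher by 0.32, and with IFN-λ4 the difference of 0.02 lay inside the random range, or past it at 0.14 with the mean of a gene's probes. The time differences of IFN-λ1 and IFN-λ4 were not tested against each other, with 6 members at least 2-fold higher and 0 lower at 16 h for IFN-λ1 and 6 higher and 3 lower for IFN-λ4. The median of IFN-α minus the mean of the IFN-λ pair was -1.41. IFIT1 went from 229-fold above untreated at 6 h to 19.9-fold at 16 h with IFN-α, and from 56.4-fold to 90.5-fold with IFN-λ1. BST2, which tethers virus particles to the cell, was higher at 16 h with each interferon, by 1.38, 1.69 and 1.37 log2 units for IFN-α, IFN-λ1 and IFN-λ4. With IFN-α, NF-κB targets (-0.80), heat shock genes and metallothioneins (-1.06), immediate early genes (-0.55), chemokines and cytokines (-0.57) and interferon-γ type targets (-0.98) were also lower at 16 h, the last of these not with a mean over probes (-0.24) or without genes below the 50th percentile (-0.45). With IFN-λ4, heat shock genes and metallothioneins (-0.30) and chemokines and cytokines (-0.33) were lower at 16 h as well, the latter inside the range of random lists without the filter on dim genes (-0.14).

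Genes at least 2-fold higher at 16 h than at 6 h with all 3 interferons numbered 8 and genes lower 11. Besides BST2, the kinase ROCK1 was higher by 1.48, 1.44 and 2.88 log2 units, IK by 1.37, 1.46 and 1.62, DGCR5 by 1.09, 1.35 and 1.55, and the clotting factor subunit F13B by 2.06, 1.06 and 1.28. CYP1B1, an oxidase induced through the aryl hydrocarbon receptor, was lower by -1.70, -2.06 and -2.71, the tubulin gene TUBA1A by -2.42, -1.47 and -1.50, F2RL2 by -3.02, -1.36 and -1.43, the small heat shock protein HSPB8 by -1.69, -1.31 and -1.45, and SOCS2, a feedback inhibitor of cytokine signalling, by -1.66, -1.18 and -1.21. In total 551 genes were higher and 505 lower with IFN-α, 64 and 68 with IFN-λ1, and 203 and 131 with IFN-λ4. Over the 6 treated arrays limma found 0 higher and 0 lower genes after Benjamini-Hochberg adjustment, with 1941 at an unadjusted p under 0.05. Adjusted over the list alone, 4 antiviral effectors were higher at 16 h (IFI6 by 1.44, OAS3 by 1.14, IFITM3 by 1.08 and BST2 by 1.48), against a median of -0.21 over the 51 members. Lower by the same adjustment were 4 NF-κB targets (RELB, TNFAIP2, CXCL8 and CXCL1, from -0.95 to -0.83) and 4 immediate early genes (FOSB by -0.64, JUNB by -0.66, JUND by -0.55 and ZFP36 by -0.81). In other lists it called TYK2, ERAP1, FGA, F2, NR1H4 and LUM higher at 16 h, and SOCS2, CYP1A1, PDGFRB and VWF lower. The count adjusted over all genes depended on single interferons: without the IFN-α arrays it was 1180 higher and 1488 lower, with 1 residual degree of freedom, and without the IFN-λ4 arrays 11 and 21.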

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

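The test of extreme untreated spots was chosen after the result was seen, as were the test of response to interferon at those spots and its bound, while the 2 tests of the IFN-α calls were chosen before.

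These results stand out because a direct limma test of the difference between 2 interferons, with time as a block and Benjamini-Hochberg adjustment, passed at an adjusted p between 0.0061 and 0.0426. IFN-λ4 minus IFN-α was -4.18 for MT1A, -5.33 for MT1B, -2.87 for PSMB9, -2.64 for SLC15A3, -3.90 for ARHGAP31, -1.93 for UBE2L6, -2.45 for RPA3 and -3.13 for DUOX1, and 2.53 for ZSWIM1 and 2.34 for CHAC1. IFN-λ1 minus IFN-α was -6.70 for MT1B, -4.88 for MT1A, -3.11 for PSMB9, -4.40 for ARHGAP31, -3.85 for DUOX1 and -2.58 for SLC15A3. Each difference had its sign at 6 h and at 16 h, with 1 array per interferon and time. Calls in both directions ended under other settings: IFN-λ4 minus IFN-α gave 1 higher and 5 lower genes with the deposited scaling or without the variance trend, and 0 and 3 without genes below the 50th percentile (1003 at an unadjusted p under 0.05 in limma).

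The IFN-α arrays had more 2-fold differences from untreated than the IFN-λ arrays. Noise of dim spots is argued against, since the ratio of calls per array was 3.68 among the brightest 4279 genes and 4.80 among the dimmest 4278. Error of single spots stays open, because a second probe of the same gene pointed the same way for 72.6% of IFN-α calls, between the bounds of 60 and 75 set in advance, against 70.0% for IFN-λ. Over all 3095 genes with a second probe, 38.1% to 61.8% pointed that way on the IFN-α arrays, by array and direction. The second probe was itself at least 2-fold that way for 28.2% of IFN-α calls and 31.7% of IFN-λ calls. A stronger effect of IFN-α at the dose used, a different dose relation and a difference in handling of its arrays cannot be told apart with 1 array per condition.

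Among the 15 genes that limma called between treated and untreated arrays, the 5 with the largest difference, MPEG1, LRRC20, TMEM165, MAP3K2 and ADIPOQ, had 1 extreme value on the untreated array. Faulty spots on that array stay open: 5 probes were in the lowest 5 percent of that array alone and above the median on all others, against at most 2 on any other array, but 4 of the 5 are the spots that prompted the test. Probes over 20 times every other array numbered 2 there and 3 on the IFN-α array of 6 h. A response to interferon stays open as well. The median SD of these genes over the treated arrays was 0.304 times that of the other called genes, which was 0.685, and an equal response to all 3 interferons at both times would also give a small spread.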

How the results depend on the processing

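Keeping the deposited scaling, leaving out extreme untreated spots and leaving out the IFN-α array of 16 h were tests chosen after seeing the data. Below, counts are genes at least 2-fold from untreated unless said otherwise, and where no reason is given the cause was not tested.

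Among list medians 2208 values kept their direction and side of the random range, 67 fell back inside it, 47 newly left it and 14 reversed. Among means of named genes 744 stayed within their spread and 29 moved, and 41 correlations stayed and 1 moved. Within 1.5 times the reported count stayed 33 counts of higher genes, 28 of lower genes, 17 of genes higher at both times and 14 of genes lower at both times, with 21, 26, 10 and 13 outside it. Of limma counts 33 higher and 35 lower stayed, and 16 and 14 did not.

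Under median centring 448 genes were higher with IFN-λ4 at 6 h, and limma gave 2 higher and 21 lower genes for IFN-λ1 minus IFN-α. List medians that changed sign were hepatocyte secreted proteins with IFN-α at 6 h (0.20) and for 16 h minus 6 h with IFN-α (-0.31) and IFN-λ4 (-0.069), cholesterol biosynthesis with IFN-α (0.045) and IFN-λ4 (0.13) at 6 h, for IFN-λ4 minus IFN-λ1 at 6 h (0.076) and for 16 h minus 6 h with IFN-α (-0.36) and IFN-λ4 (-0.052), and cell cycle with IFN-α at 6 h (0.11) and for IFN-λ4 minus IFN-λ1 at 6 h (0.14). The cause was not tested.

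With the deposited scaling kept, lower genes numbered 563 with IFN-α at 6 h, 50 with IFN-λ1 at 16 h, 312 and 46 with IFN-λ4 at 6 h and 16 h, and 11 with IFN-λ4 at both times. limma gave 1 higher and 5 lower genes for IFN-λ4 minus IFN-α, and the median of nucleic acid sensing with IFN-λ4 at 16 h was -0.036. The cause was not tested.

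With no filter on dim genes, where more genes were tested, higher genes numbered 1114 with IFN-α at 16 h, 237 and 219 with IFN-λ1 at 6 h and 16 h, and 409 and 220 with IFN-λ4. Lower genes numbered 158 and 92 with IFN-λ1 and 254 and 83 with IFN-λ4. At both times 421, 133 and 164 genes were higher with IFN-α, IFN-λ1 and IFN-λ4, and 28 and 20 lower with IFN-λ1 and IFN-λ4. limma gave 2 lower genes for treated against untreated, 1 higher for IFN-λ4 minus IFN-λ1 and 1 higher for IFN-λ1 minus IFN-α. The correlation of IFN-λ4 with IFN-λ1 at 6 h was 0.62, and the antiviral median for IFN-λ1 minus IFN-α at 16 h was 0.19, inside the random range.

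With genes below the 50th percentile left out, and so fewer genes tested, IFN-α had 292 higher and 235 lower genes at 6 h, 409 and 291 at 16 h, and 144 and 66 at both times. IFN-λ1 had 44 and 14 lower genes at 6 h and 16 h and 4 at both times, and IFN-λ4 had 166 higher and 98 lower at 6 h and 2 lower at both times. limma gave 0 lower genes for treated against untreated (181 at an unadjusted p under 0.05), 0 higher and 3 lower for IFN-λ4 minus IFN-α (1003) and 3 lower for IFN-λ1 minus IFN-α. Medians that changed sign were chemokines and cytokines with IFN-λ4 at 6 h (-0.019) and 16 h (-0.24) and nucleic acid sensing with IFN-λ4 at 16 h (-0.090).

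At a 1.5-fold threshold, which by construction admits more genes, higher and lower genes numbered 1419 and 1226 with IFN-α at 6 h, 1558 and 1803 at 16 h and 694 and 549 at both times, 676 and 626, 425 and 333, and 187 and 88 with IFN-λ1, and 1040 and 925, 362 and 304, and 248 and 99 with IFN-λ4. At 3-fold, which admits fewer, they numbered 179 and 88, 360 and 56, and 101 and 12 with IFN-α, 50 and 10, 57 and 3, and 41 and 3 with IFN-λ1, and 76 and 20, 60 and 2, and 51 and 1 with IFN-λ4.

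With values under the 30th percentile set to it, limma gave 2 lower genes for treated against untreated and 1 higher for IFN-λ4 minus IFN-α, and the antiviral median for IFN-λ1 minus IFN-α at 16 h was 0.19. With the mean of a gene's probes, IFN-λ4 had 17 lower genes at 16 h and 2 at both times, limma gave 1 higher gene for IFN-λ4 minus IFN-λ1 and 14 lower for IFN-λ1 minus IFN-α, and the antiviral median for 16 h minus 6 h with IFN-λ4 was 0.14, past the random range. Without the variance trend limma gave 1 higher and 5 lower genes for IFN-λ4 minus IFN-α. With no time block it gave 1 higher for IFN-λ4 minus IFN-α and 14 lower for IFN-λ1 minus IFN-α. The cause was not tested.

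Without the IFN-α arrays limma gave 36 higher genes for treated against untreated and 1180 higher and 1488 lower for 16 h minus 6 h, and without the IFN-λ4 arrays 9, 11 and 21. Without the IFN-α array of 16 h it gave 757 higher and 1028 lower genes for IFN-λ1 minus IFN-α, 685 and 778 for IFN-λ4 minus IFN-α and 2 higher for IFN-λ4 minus IFN-λ1. These fits had fewer arrays, and for times and interferons 1 residual degree of freedom, where the lone IFN-α array was assumed to vary like the others.

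Signal over background limits dim genes such as IFNLR1 and IRF7, and with 1 array per condition a 2-fold difference at 1 time had no check.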

Other observations

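The genes in the next 2 paragraphs and the test of splits were chosen after the values were seen, and the tests of the IFN-λ times were chosen before.

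Some genes of the stress list and of other lists moved with IFN-α at 1 time more than at the other. HMOX1, which breaks down haem, was 22.6-fold higher than untreated at 6 h and 1.62-fold at 16 h, against 1.71-fold with IFN-λ1 and 2.27-fold with IFN-λ4 at 6 h. The inducible heat shock protein HSPA1A was 2.76-fold higher at 6 h and 3.17-fold lower at 16 h with IFN-α, and HSPA1B was 1.74-fold higher and then 4.42-fold lower (the 2 are close paralogs). ENO2, a glycolytic enzyme, was 4.52-fold higher with IFN-α at 16 h and 2.83-fold lower with IFN-λ1 at 6 h. IL15, a cytokine for natural killer cells, was 8.50-fold higher with IFN-α at 6 h and 1.21-fold at 16 h.

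On the 4 IFN-λ arrays alone, limma called 2668 genes between 16 h and 6 h, with 1 residual degree of freedom, a median absolute difference of 0.59 log2 units and 148 genes at least 2-fold apart. IFI6 rose by 1.94 ± 0.12 (SE, adjusted p = 0.000146, limma with Benjamini-Hochberg adjustment, higher at 16 h with both IFN-λ). CYP1A1, an oxidase induced through the aryl hydrocarbon receptor, decreased by 1.83 ± 0.11 (adjusted p = 0.000146, limma), CCNG2, an atypical cyclin, rose by 1.82 ± 0.21 and CCN1, a matrix protein, decreased by 1.45 ± 0.16. With IFN-α the differences were 0.45 for IFI6, -0.45 for CYP1A1, 0.72 for CCNG2 and 0.00 for CCN1. RPS28 had a difference of -8.35 with an SE of 2.62.

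The IFN-λ arrays of 6 h differed from those of 16 h at many genes. Genes that respond to interferon were tested as its source. The bound set in advance was whether most of the called genes lay at least 2-fold from untreated on an IFN-λ array. That held for 9.82% of them, which is on the side of the bound against this source. Their median difference between times was 0.59 log2 units, so a gene could respond and be called without reaching 2-fold. That limit was not set in advance, and because of it this source is left open. A factor common to all 6 h arrays, such as time in culture or a shared batch, stays open: the correlation across genes of the time difference with IFN-α and with IFN-λ was 0.138 (rho 0.10), between the bounds of 0.1 and 0.3 set in advance, and genes are not independent replicates. IFN-λ1 and IFN-λ4 gave r = 0.56. Time and any batch cannot be told apart here.

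For the comparison of 16 h with 6 h over all 6 treated arrays, which gave 0 genes in limma after Benjamini-Hochberg adjustment and 1941 at an unadjusted p under 0.05, the 10 splits into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes and the highest other split 36.

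Each array was also set alone against the rest in limma. Each of these fits had 1 array in 1 arm and took its spread from a mixture of the other conditions. Their counts rank no array and are not given.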
